A study of Rattus norvegicus with 9 samples.

How the data were processed

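Small RNAs of rat (Rattus norvegicus) striatum were measured in 9 libraries, 3 from each of 3 groups: corn oil control, MMT and MnCl2. Per the labels' protocols, RNA was extracted with TRIzol, a gel band of 15 to 45 nucleotides was taken, and libraries were made with the QIAseq miRNA kit, which carries unique molecular identifiers. Per the submitters' processing notes, reads were trimmed with Trimmomatic (version not given) and the genome build was rn6. The aligner, the mismatches allowed, the placement of reads that fit several sequences, the use of strand and the use of molecular identifiers are not given in the sources used here. If identifiers were not used, counts include PCR copies, and the spread between libraries covers more than counting error.

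The authors deposited raw counts, with 1 column per library and no normalization, as the whole numbers and unequal totals show. Each library lists the same 1759 entries: 764 miRNAs, 585 piRNAs and 410 tRNA genes. Totals ran from 583045 to 2012769, and entries with few counts have correspondingly wide errors. tRNA coordinates are those in the entry names, for which the notes name rn6, and were not checked against a genome here; a start above the end marks the minus strand. Sequences of 16 shared bases marked a piRNA as lying within a tRNA. Host genes of miRNAs were looked up in the RefSeq table of the GRCr8 assembly, from which no coordinates are given.

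Groups and replicate numbers were taken from the sample titles and treatment labels. The comparisons, lists, tests and most alternatives were fixed before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, robust quasi-likelihood fit, two-sided), with all 9 libraries in 1 fit and Benjamini-Hochberg adjustment at 0.05. The filter left 1113 entries (615 miRNAs, 410 tRNA genes, 88 piRNAs), and the 646 others held 0.0854% of counts. The biological coefficient of variation was 0.279. Levels are CPM scaled by TMM, as mean ± SD. Summed isotype levels come from a separate fit, of entries that share sequence summed, with its own TMM scaling. They are not on one scale with the levels of single genes. Lists of at least 3 members were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over 56 lists. These were 17 miRNA lists (neuron, activity, Dlk1-Dio3, oligodendrocyte, immune, erythrocyte, endothelial, choroid plexus, Hox, muscle, let-7, miR-29, miR-30, miR-17/92, miR-34, hypoxia and alpha-synuclein) and 39 tRNA isotypes. All adjusted p-values of lists are from camera unless fry, also of limma, is named. Class shares and totals were compared by exact two-sided permutation tests over 20 arrangements.

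Entries named in the text follow a fixed rule: those past the threshold, up to 10 higher and 10 lower, and where fewer than 5 passed in a direction, the next lowest p up to 5. For MMT against MnCl2 the limits were 5 and 5. The 5 most abundant entries and, for each list, its members past the threshold or else its 2 most abundant were added. Levels of further markers given per library were chosen after the values were seen.

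Alternatives were DESeq2 1.42.0, RLE or total-count scaling, no filter or a stricter one (10 CPM in 3 libraries), the 2 compared groups alone, each library left out, the replicate number as a block, miRNAs alone, the most abundant entry left out of the class shares, a fold threshold of 2, a fit without robust weights, an estimated correlation and fry. The total count as a covariate, entries that share sequence summed, and fold changes by abundance were added after the data were seen. Overlaps at an unadjusted p under 0.05 were set against 100 simulations of unchanged groups that shared simulated controls, and against 100 redraws of the labels, chosen after the data were seen. Medians of miRNA lists were set against 10000 random lists, each member drawn from the 50 other miRNAs nearest in abundance, which do not keep the correlation between members. Antisense partners within a list were kept as separate members. Scripts were tested on simulated data of 1113 entries, with 200 changed in each of 5 simulations. They recovered 23.6% of 1.5-fold, 51.9% of 2-fold and 80.6% of 4-fold changes, 26 of 545 calls were false, and 4 of 5 moved lists were called with 0 others. Simulated entries were drawn independently, without the structure between the real libraries. The list result therefore cannot show how camera fares on correlated members, and the estimated correlation had a median of 0.153 in miRNA lists and 0.417 in isotypes. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.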

Results

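Small RNAs of the rat striatum were sequenced after 8 weeks of oral dosing with manganese. The striatum is the input nucleus of the basal ganglia and a known site of manganese injury. Rats received the organic compound methylcyclopentadienyl manganese tricarbonyl (MMT, a fuel additive) at 4 mg/kg, equal to about 1 mg of manganese per kg, in corn oil. Others received manganese chloride (MnCl2, as the tetrahydrate) at 200 mg/kg in saline as the positive control, and the control group received corn oil at 1 ml/kg. Doses were given by gavage once a day on 6 days a week. Each group had 3 libraries, 9 in all, from a series of 18 rats of both sexes. The sex behind each library, and whether a library came from 1 rat or from a pool, are not given in the labels, so p-values measure only the spread between these libraries, which may be technical. Total counts ran from 583045 in control 3 to 2012769 in control 1. The group means were 1200700 ± 734000 for control, 1167320 ± 410000 for MMT and 889630 ± 122000 for MnCl2 (SD, n = 3). No difference in totals was found by an exact two-sided permutation test (MMT against control p = 1, MnCl2 against control p = 0.7, MMT against MnCl2 p = 0.4), in a design where 3 against 3 allows no p below 0.1.

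Among the most abundant small RNAs of the striatal libraries were brain miRNAs and fragments of glycine, lysine, glutamine and aspartate tRNAs. The 10 most abundant entries held 23% to 27.2% of a library's counts. In control libraries, miR-29b-3p stood at 32772 ± 7481 CPM (counts relative to the library total, scaled by TMM), let-7f-5p at 27995 ± 6005 and the neuronal miR-9a-5p at 26769 ± 4891 (SD, n = 3). Summed over their gene copies, tRNA-Gly-GCC genes held 61050 ± 2748 CPM, tRNA-Lys-CTT 27137 ± 2041 and tRNA-Gln-CTG 25507 ± 5043 in the same libraries. There tRNA-Asp-GTC held 20665 ± 7202. It stood above Gln-CTG in MMT (22524 ± 5470 against 20011 ± 1280) and MnCl2 libraries (23738 ± 5350 against 17661 ± 1574). By class, miRNAs took 59.7% ± 3.49 of control counts, tRNAs 38.6% ± 3.46 and piRNAs 1.68% ± 0.119 (SD, n = 3). MMT libraries held 60.9% ± 3.74 miRNA, 37.4% ± 3.56 tRNA and 1.7% ± 0.204 piRNA, and MnCl2 libraries 62.1% ± 3.36, 36.4% ± 3.19 and 1.53% ± 0.17. No difference in class share was found in exact two-sided permutation tests (MMT against control p = 0.7, 0.7 and 0.9 for miRNA, tRNA and piRNA; MnCl2 against control p = 0.5, 0.5 and 0.3; MMT against MnCl2 p = 0.6, 0.7 and 0.3). The smallest p that 3 against 3 allows is 0.1, and after Benjamini-Hochberg adjustment over the 3 classes the exact values ran from 0.5 to 0.9.

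Many of the named small RNAs share their sequence, or its complement, with another entry. Of 764 miRNA entries, 106 had another miRNA as an antisense partner, and these held 52% of the miRNA counts. The total over the 9 libraries was 269107 for miR-9a-5p and 269357 for its antisense partner miR-9b-3p, and 265766 for miR-29a-3p and 265952 for its partner miR-3556a. Of 410 tRNA genes, 221 had an identical copy. Of 585 piRNA entries, 90 lay within a tRNA sequence, sharing 16 bases or more, and these 90 held 88% of piRNA counts. Levels of single members of such sets are therefore uncertain, and tRNA genes were also summed by isotype.

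**Figure D1:**
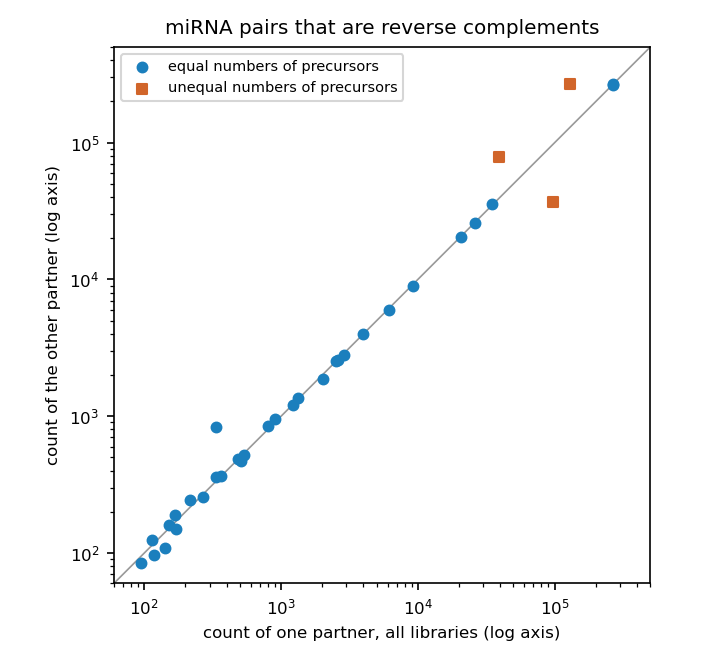
Counts of 34 pairs of miRNA entries that are reverse complements, summed over the 9 libraries, one partner on each log axis, with a line of equality. Pairs with equal numbers of precursors and 1000 counts or more lie near the line (miR-9a-5p and miR-9b-3p at 269107 and 269357), and let-7f-5p with its partner miR-3596d, at 267464 and 128595, lies off it.

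The largest difference among the libraries ran across the groups and followed the total count. The first principal component held 64.4% of the variance and placed control 1, the deepest library, at one end, and control 3, MMT 2 and MnCl2 2 at the other. Its score correlated with the log2 total (Pearson r = -0.949, exact permutation p = 0.000102; Spearman rho = -0.983, exact permutation p = 4.96e-05; n = 9). Adjusted over the 2 relations computed between a measure and the total, the exact p-values were 0.000204 and 9.92e-05. Without control 1 and control 3, the libraries farthest from the median total, r was -0.929 (exact permutation p = 0.00258, n = 7). The labels give no sequencing batch, so none could be tested.

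**Figure D2:**
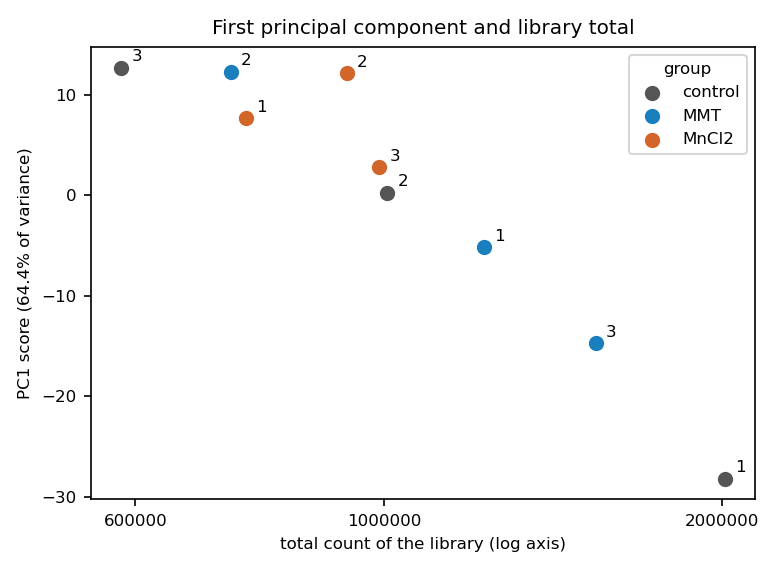
Score on the first principal component of log2 CPM against the library's total count (log axis), 1 point per library, numbered by replicate and coloured by group. The deepest library, control 1 at 2012769 counts, has the lowest score, and the shallowest, control 3 at 583045, has the highest.

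The comparison of MMT with control addressed whether the organic compound, given in the same vehicle as the control, was accompanied by a change in striatal small RNAs. The lowest p-value belonged to miR-301b-3p (cagtgcaatggtattgtcaaagc), of the miR-130/301 family. It was at 52.4 ± 6 CPM in control and 24.2 ± 1.31 CPM in MMT libraries, against 42 ± 4.36 in MnCl2 libraries (SD, n = 3; log2 fold change MMT against control -1.11, SE 0.27, edgeR adjusted p = 1). All 3 MMT libraries, at 23 to 25.6 CPM, lay below the 3 control libraries, at 48.9 to 59.3. The scarce other arm, miR-301b-5p, did not share this separation. It was at 0.557, 6.85 and 16.7 CPM in the control libraries and 8.53, 20.1 and 3.55 in the MMT libraries. The related miR-301a-3p ran from 911 to 1380 CPM in control and from 1018 to 1638 in MMT. A mitochondrial leucine tRNA (anticodon TAA, chromosome M, 2665 to 2739), whose human counterpart carries a frequent MELAS mutation, was at 9215 ± 3393 CPM in control, 4903 ± 1296 in MMT and 5384 ± 1117 in MnCl2 libraries (SD, n = 3). Glutamine tRNA with anticodon CTG was lower as a group, with all 10 gene copies negative and a median log2 fold change of -0.47, and its summed level was 20011 ± 1280 CPM against 25507 ± 5043 in control (SD, n = 3). This group passed with camera at the preset correlation (adjusted p = 4.23e-08) and not otherwise (adjusted p = 0.911 with an estimated correlation).

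None of these single differences passed the correction. The edgeR test called 0 of 1113 entries (24 at an unadjusted p under 0.05, of which 22 were lower and 2 higher; 33 lower and 26 higher with the total count as a covariate), and DESeq2 called 0 as well (24 at an unadjusted p under 0.05). Among the 615 miRNAs 4 were lower and 2 higher at that level (5 and 0 with miRNAs scaled alone), among the 410 tRNA genes 13 were lower, and among the 88 piRNAs 5 were lower. Of these 13 tRNA genes, 6 were copies of Gln-CTG, which move together (estimated correlation 0.955). With entries that share sequence summed, 5 were lower and 1 higher at an unadjusted p under 0.05. In simulations of unchanged groups, medians of 25 lower and 24 higher entries reached that level. Simulated data with the same library totals gave back 23.6% of 1.5-fold, 51.9% of 2-fold and 80.6% of 4-fold changes. There, 200 entries changed each time and entries were drawn independently, without the structure that followed the total count. Recovery in the real data may differ. After miR-301b-3p, the lowest p-values among lower entries were those of miR-320-5p (299.7 ± 45.5 against 194.5 ± 42.4 CPM, log2 fold change -0.62, SE 0.18), whose precursor escapes Drosha cleavage, and of miR-187-3p (953 ± 91.4 against 713 ± 69.7, log2 fold change -0.42, SE 0.13). The mitochondrial leucine tRNA followed with a log2 fold change of -0.91 (SE 0.29), and then a tRNA-Gln-CTG gene on chromosome 17 (58796727 to 58796798) at 1358 ± 324 CPM in control and 889 ± 142 in MMT (log2 fold change -0.61, SE 0.21). Higher in MMT were miR-874-3p (4.73 ± 2.17 against 12.7 ± 1.77 CPM), miR-18a-5p of the miR-17/92 cluster (18.7 ± 6.09 against 33.5 ± 9.39), the liver miRNA miR-122-5p (6.29 ± 3.85 against 13.4 ± 5.18), the tRNA-derived pir-87165 (433.7 ± 22.3 against 511.7 ± 40.4) and a tRNA-Gly-CCC gene on chromosome 2 (217947735 to 217947805; 3957 ± 1395 against 5712 ± 1643). Their log2 fold changes were 1.48, 0.88, 1.15, 0.24 and 0.53, each with an edgeR adjusted p of 1. For miR-301b-3p, 1 base separates it from miR-301a-3p, which had 12785 counts against its 373 in all libraries, so reads crossing between them could not be excluded.

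**Figure D3:**
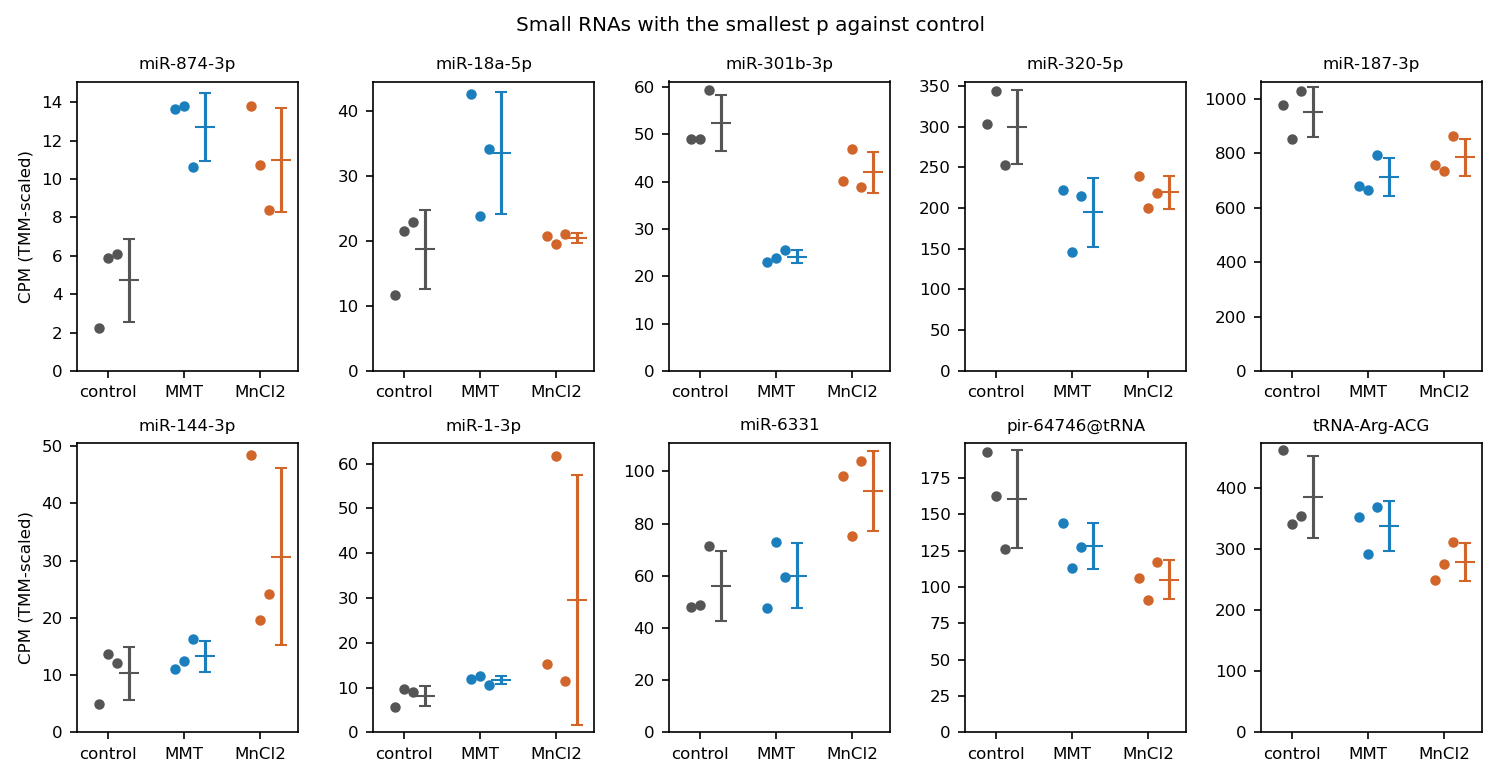
CPM (TMM-scaled) per library in the 3 groups, with the group mean and SD beside the points, for 10 small RNAs of low unadjusted p against control: 5 from the MMT comparison (top) and 5 from the MnCl2 comparison (bottom). Each 5 combine the lowest p among higher and among lower entries, so the choice is not by p alone. The 3 MMT libraries of miR-301b-3p lie at 23 to 25.6 CPM, and 1 MnCl2 library, at 61.6 CPM, sets the MnCl2 mean of miR-1-3p.

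By group, 8 of 56 lists passed in MMT against control with camera at a preset correlation of 0.01, all of them tRNA isotypes. Lower were Gln-CTG (adjusted p = 4.23e-08), Arg-TCG (0.000215), His-GTG (0.004), Arg-ACG (0.0121), Gln-TTG (0.0121) and Arg-TCT (0.0133), and higher were Asp-GTC (0.0261) and Pro-TGG (0.0379), which deliver glutamine, arginine, histidine, aspartate and proline. With an estimated correlation none passed (adjusted p = 0.911 with an estimated correlation for each of the 8), and fry called 0 lists. For Gln-CTG, the estimated correlation between gene copies was 0.955, and the summed isotype gave a log2 fold change of -0.35 (edgeR adjusted p = 0.998). The median log2 fold changes were -0.22 for Arg-TCG, -0.15 for His-GTG, -0.20 for Arg-ACG, -0.26 for Gln-TTG, -0.14 for Arg-TCT, 0.17 for Asp-GTC and 0.14 for Pro-TGG. No member of any list passed when adjusted over the list alone or over all entries. Without control 1 all 8 calls ended (adjusted p 0.112 to 0.724), yet 5 of the 8 medians stayed within 1.5 times their value. Those of Arg-ACG (-0.03) and Gln-TTG (-0.17) were smaller, and Asp-GTC turned lower (adjusted p = 0.299). Without MMT 2 all calls but Gln-CTG and Pro-TGG ended (0.0882 to 0.565), with smaller medians for Arg-ACG (-0.10), Arg-TCG (-0.14), Gln-TTG (-0.15) and Asp-GTC (0.01). Single calls ended without control 2 (Gln-TTG, 0.309, median -0.17), without control 3 (Arg-TCT, His-GTG and Pro-TGG, 0.132 to 0.542, medians -0.12, -0.09 and 0.11) and, for Pro-TGG alone, without MMT 1 (0.171), MMT 3 (0.754, median 0.03), MnCl2 1 (0.0657) or MnCl2 3 (0.07). With the total count as a covariate, Arg-TCT (0.0554, median -0.14) and Pro-TGG (0.223, median 0.13) did not pass. The remaining 31 isotypes had adjusted p-values of 0.0914 to 0.994. Of these, Ala-TGC passed without control 2 (0.0463), Arg-CCT, Asn-GTT, Cys-GCA, Val-CAC and Pro-AGG without control 3 (0.0276 to 0.0347), Met-CAT without MMT 2 (0.0134), and Arg-CCG and Asn-GTT without MMT 3 (0.0457 and 0.0205).

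None of the 17 miRNA lists passed in MMT against control. Closest were the oligodendrocyte-enriched miRNAs, which accompany myelin formation, with 5 of 6 members positive and a median log2 fold change of 0.27 (adjusted p = 0.0521 with camera at the preset correlation; adjusted p = 0.911 with an estimated correlation). Among the 6, miR-219a-2-3p and miR-219b are antisense partners with 6144 and 5973 counts, so the same reads may count in both. Of the list's members, miR-338-3p was at 3245 ± 811 CPM in control and 3723 ± 308 in MMT, and miR-219a-5p at 527.7 ± 56.9 and 670.0 ± 89.9 (SD, n = 3). That list passed without control 1 (adjusted p = 0.000931) or without MnCl2 2 (0.0414), and the miR-17/92 clusters (median 0.09, adjusted p = 0.219) passed without control 2 (0.0476) or MMT 3 (0.0432). Neuron-enriched miRNAs had a median of 0.05 (adjusted p = 0.382), with miR-128-3p at 19384 ± 2709.8 CPM in control and 19463 ± 2699.8 in MMT. Activity-regulated miRNAs had a median of -0.07 (0.577), with miR-132-3p at 671.6 ± 115 and 698.8 ± 44.7, and the imprinted Dlk1-Dio3 cluster 0.00 (0.994). Immune miRNAs had a median of 0.14 (0.161), with miR-21-5p at 1541 ± 458 and 1889 ± 226, erythrocyte miRNAs 0.08 (0.793), endothelial and smooth-muscle miRNAs 0.06 (0.668) and hindbrain Hox miRNAs 0.06 (0.915). The alpha-synuclein-targeting miRNAs had a median of 0.06 (0.636), with miR-7a-5p at 24843 ± 3741 and 25930 ± 6587. The let-7 family had -0.03 (0.719, camera direction up), miR-29 0.01 (0.746, direction down), miR-30 0.03 (0.994, direction down), miR-34 0.07 (0.651) and hypoxia miRNAs 0.03 (0.6), and choroid plexus miRNAs 0.06 (0.972, direction down) and muscle miRNAs -0.07 (0.978, direction up). Among 10000 random miRNA lists of like abundance, the medians stood at the 99.6 percentile for oligodendrocyte miRNAs, at 0.6 for let-7 and at 3.82 to 91.9 for the remaining 15.

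MnCl2, the positive control, was compared with control in turn, with a different vehicle, so that compound and vehicle cannot be separated here. Scarce entries of both classes mostly had higher values (185 of 215 miRNAs and 6 of 8 tRNA genes at 20 CPM or less, and 34 of 41 tRNA genes at 20 to 50 CPM), and 13 tRNA isotypes were lower with camera at the preset correlation (adjusted p = 0.627 to 0.696 with an estimated correlation). The erythroid miR-144-3p was at 30.7 ± 15.5 CPM against 10.3 ± 4.64 in control (log2 fold change 1.6, SE 0.54), and the muscle miRNA miR-1-3p at 29.5 ± 27.9 against 8.16 ± 2.27 (1.89, SE 0.66), each with n = 3 and an edgeR adjusted p of 0.843. MnCl2 1 held the highest level of miR-144-3p, 48.4 CPM against 19.6 and 24.1 in the other two MnCl2 libraries, and the more abundant erythroid miR-451-5p was at 49.3 ± 26 against 45 ± 15.3 CPM (log2 fold change 0.13, SE 0.40, edgeR adjusted p = 0.959). Glutamine tRNA with anticodon CTG summed to 17661 ± 1574 CPM against 25507 ± 5043, and arginine tRNA with anticodon ACG to 1752 ± 84 against 2572 ± 609.5 (SD, n = 3). All 10 and all 6 of their gene copies were negative, with median log2 fold changes of -0.40 and -0.39. The sums come from the separate fit of summed entries, in which most isotypes were lower in MnCl2. Leu-CAG, not called as a list, had a summed log2 fold change of -0.22 and a gene median of -0.06. A lower sum is therefore not particular to these isotypes.

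The edgeR test again called 0 of 1113 entries, with a lowest adjusted p of 0.843 (51 at an unadjusted p under 0.05, 16 higher and 35 lower), and DESeq2 called 0 (75 at an unadjusted p under 0.05). Which direction prevailed at that level depended on the setting, with 78 higher and 36 lower with the total count as a covariate, 47 and 36 without the low-count filter, 18 and 12 without control 1, and 29 and 11 without MnCl2 2. Without the low-count filter 1 miRNA was called, the epithelial miR-200a-3p, singled out after its values were seen, with counts of 12, 6 and 5 in control and 39, 63 and 7 in MnCl2 libraries (log2 fold change 2.48, SE 0.56, edgeR adjusted p = 0.0189; 0.843 with the filter). Of the 615 miRNAs 14 were higher and 2 lower at that level, which turned to 2 higher and 9 lower with miRNAs scaled alone, of the 410 tRNA genes 1 higher and 23 lower, and of the 88 piRNAs 1 higher and 10 lower. Among the 23 lower tRNA genes, 5 were copies of Gln-CTG. With entries that share sequence summed, 5 were higher and 21 lower at an unadjusted p under 0.05. The median log2 fold change was 0.23 for miRNAs, -0.08 for tRNA genes and -0.23 for piRNAs. Scaling on miRNAs alone moved the miRNA median to -0.05, and gave -0.10 for MMT against control in place of 0.04, so the sign of a miRNA list median within that shift rests on the scaling. Among miRNAs the median was 0.48 at 20 CPM or less (185 of 215 positive) and 0.02 above 1000 CPM, and 0.41 (173 positive) and 0.13 with the total count as a covariate. With miRNAs scaled alone these medians were 0.21 (144 of 211 positive) and -0.26. Among tRNA genes the median was 0.30 at 20 CPM or less, 0.21 at 20 to 50 CPM and -0.13 above 1000 CPM. Also higher in MnCl2 were miR-6331 (56.1 ± 13.4 in control, 92.5 ± 15.1 CPM in MnCl2; log2 fold change 0.73), miR-489-5p (6.99 ± 3.25 and 21 ± 9.26; 1.66) and pir-178901 (2.51 ± 2.07 and 12.7 ± 1.05; 2.33). Lower were pir-64746 (160.6 ± 33.5 and 105 ± 13.4 CPM; -0.62), which shares 16 bases or more with valine and alanine tRNA entries, and pir-72949 (324 ± 72.7 and 223 ± 48.1; -0.54), which does so with tRNA-Asp-GTC. So were pir-64205 of lysine tRNA (237 ± 113 and 135 ± 28.4; -0.82), a tRNA-Arg-ACG gene on chromosome 15 (37051458 to 37051530; 386.5 ± 67.1 and 279 ± 31; -0.47) and a tRNA-Ile-TAT gene on chromosome 17 (58772987 to 58772894, minus strand; 332 ± 25.5 and 254 ± 26.8; -0.39). The direction of pir-72949 was opposite to that of the 15 tRNA-Asp-GTC genes, which were all positive in MnCl2 (median log2 fold change 0.32). The mitochondrial leucine tRNA had a log2 fold change of -0.77 (SE 0.29) and the summed mitochondrial glutamine tRNA -0.53 (11149 ± 929 against 16075 ± 2391 CPM, edgeR adjusted p = 0.993). For miR-1-3p, 1 base separates it from miR-1b, and its counts were 11, 63 and 11 in MnCl2 1, 2 and 3.

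With camera at the preset correlation, 17 of 56 lists passed in MnCl2 against control. Lower were 13 tRNA isotypes: Gln-CTG (adjusted p = 1.2e-06), Arg-ACG (0.000201), His-GTG and Lys-CTT (0.00043 each), Trp-CCA (0.000767), Cys-GCA and Asn-GTT (0.00546 each), Ile-TAT (0.00579), Arg-CCT (0.0237), Arg-TCG and Val-CAC (0.0366 each), Arg-TCT (0.0436) and Thr-CGT (0.0439). Asp-GTC was higher (0.00923, median 0.32), as were muscle miRNAs (0.016), choroid plexus and epithelial miRNAs (0.0254) and hypoxia and oxidative stress miRNAs (0.0279). None passed when the correlation was estimated (adjusted p = 0.627 to 0.726 with an estimated correlation), and fry called 0. Adjusted over the list alone, 2 of the 3 Ile-TAT genes were lower (the smaller p 0.0369), and 0 members of the remaining lists passed. Gln-CTG, Arg-ACG, His-GTG and Lys-CTT were the 4 calls that held whichever library was left out, though their medians moved. Gln-CTG (-0.40 with all libraries) was at -0.31 without control 1 and -0.66 without control 3. Lys-CTT went from -0.13 to -0.21 without control 3, and His-GTG from -0.19 to -0.11 without MnCl2 1. Without control 1, 11 of the 17 calls ended (adjusted p 0.0607 to 0.981, Trp-CCA at 0.0608), with medians within 1.5 times for 4 and smaller ones for Asp-GTC (0.02), Cys-GCA (-0.01), Trp-CCA (-0.16), Val-CAC (-0.08) and the 3 miRNA lists. Without control 2, 7 ended (0.0538 to 0.174), although 6 of the medians stayed within 1.5 times and that of Arg-TCT was larger (-0.18 in place of -0.12). Without MnCl2 2, 8 ended (0.0542 to 0.135), with smaller medians for Arg-TCG (-0.10), Arg-TCT (-0.05), Asn-GTT (-0.04), Asp-GTC (0.19) and muscle miRNAs. Losses were fewer without control 3 (3 calls, 0.0533 to 0.137), MnCl2 1 (2 calls, 0.163 and 0.324), MnCl2 3 (5 calls, 0.0577 to 0.151) and MMT 3 (Thr-CGT, 0.0511). With the total count as a covariate, Arg-CCT (0.0612), Arg-TCG (0.0831), Thr-CGT and Val-CAC (0.066 each) and the choroid plexus list (0.139) did not pass, while all 5 medians stayed within 1.5 times their value. Of the isotypes not called, Gln-TTG passed without control 3 (0.00374) or MnCl2 1 (0.0136), Glu-CTC without MnCl2 2 (0.0404), and Ala-TGC, Glu-TTC, Ser-AGA, Ser-GCT and Ser-TGA without MnCl2 3 (0.00251 to 0.0415).

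**Figure D4:**
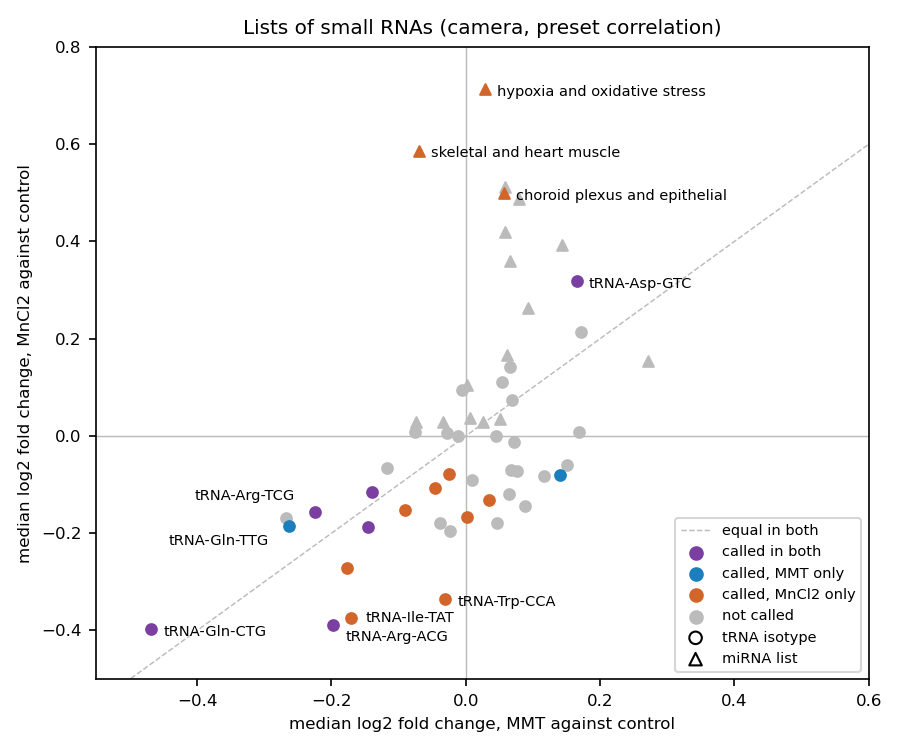
Median log2 fold change of each of 56 lists in MMT against control (horizontal) and MnCl2 against control (vertical); circles are tRNA isotypes, triangles miRNA lists, colours show camera calls at the preset correlation, and the dashed line marks equal values. Gln-CTG lies at -0.47 and -0.40, and the muscle, choroid plexus and hypoxia lists lie at 0.59, 0.50 and 0.71 on the MnCl2 axis.

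Each of the 3 miRNA lists that were higher in MnCl2 lost its call without any of several single libraries. Muscle miRNAs had 10 of 12 members positive (median 0.59), with miR-1b at 280.1 ± 191 CPM against 154.5 ± 102 in control, and MnCl2 2 alone at 497.8 (SD, n = 3). Its call ended without MnCl2 2 (adjusted p = 0.107, median 0.19), control 1 (0.0607, median 0.15) or control 2 (0.0577, median 0.45), and its median with all libraries lay at the 89.9 percentile of 10000 random lists of like abundance. Choroid plexus and epithelial miRNAs had 16 of 20 positive (median 0.50, against 0.10 to 0.50 in 95% of such random lists), yet their most abundant members, miR-204-5p and miR-1298, were at 579 ± 496 and 292 ± 352 CPM in MnCl2 and 696 ± 342 and 319 ± 250 in control. This call ended without MnCl2 1 (0.324, median 0.49) or control 1 (0.435, median 0.19) and with the total count as a covariate (0.139, median 0.40). Hypoxia and oxidative stress miRNAs had 10 of 11 positive (median 0.71, above the 0.08 to 0.67 of 95% of such random lists). These include miR-141-5p at 51.4 ± 4.93 against 32.2 ± 27.2 CPM, and miR-34a-5p at 1521 ± 255 against 1750 ± 790, which the p53 pathway induces. The hypoxia list is not separate from others, as its miR-200a, miR-200b, miR-200c and miR-141 members are also in the choroid plexus and epithelial list. Its miR-144 members are also in the erythrocyte list, and those of miR-34a in the miR-34 list. The hypoxia call ended without MnCl2 1 (0.163, median 0.55), control 1 (0.0681, median 0.31) or control 3 (0.0533, median 1.12). The adjusted p-values of the 3 lists were 0.627, 0.696 and 0.627 with an estimated correlation.

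The remaining 14 miRNA lists did not pass in MnCl2 against control. Endothelial and smooth-muscle miRNAs had all 7 members positive with a median of 0.51, at the 100 percentile of 10000 random lists of like abundance, at an adjusted p of 0.127. Its members miR-126a-5p and miR-126b are antisense partners (20523 and 20290 counts), so the same reads may count in both. The same holds for miR-409a-3p and miR-409b of the Dlk1-Dio3 cluster (2546 and 2524 counts). MnCl2 1 carried 17930 CPM of the smooth-muscle miRNA miR-143-3p against 6624 to 9215 in the other libraries, 1329 CPM of miR-145-5p against 404.7 to 702.8, and 186.6 CPM of the myeloid miR-223-3p against 64 to 104. Erythrocyte miRNAs had a median of 0.49 (adjusted p = 0.169), immune miRNAs 0.39 (0.08), hindbrain Hox miRNAs 0.42 (0.127), the miR-34 family 0.36 (0.292) and the miR-17/92 clusters 0.26 (0.0869). The Dlk1-Dio3 cluster had 52 of 72 members positive with a median of 0.10 (0.08; 0.12 to 0.30 in 95% of such random lists, 1.15 percentile), and oligodendrocyte-enriched miRNAs had 0.16 (0.248), with miR-219a-5p at 812 ± 281 CPM. Alpha-synuclein-targeting miRNAs had a median of 0.17 (0.395), and neuron-enriched (0.04, adjusted p = 0.992), activity-regulated (0.03, 0.994), let-7 (0.03, 0.986), miR-29 (0.04, 0.992) and miR-30 (0.03, 0.852) miRNAs had medians nearer 0. Among random lists of like abundance, the immune median stood at the 94.8 percentile, miR-34 at 77.4, erythrocyte at 72.6, alpha-synuclein at 65.7, oligodendrocyte at 59, Hox at 45.1, miR-17/92 at 31.8, activity-regulated at 4.18 and the other 4 at 10.3 to 23.3. Without control 1 the Dlk1-Dio3, oligodendrocyte, immune and endothelial lists passed (0.00155, 0.00155, 0.0376 and 0.0114), and without MnCl2 2 the oligodendrocyte, immune, erythrocyte and endothelial lists did (0.0491, 0.0334, 0.0404 and 0.00776). The Hox list passed without control 3 (0.0262) and the miR-17/92 clusters without control 2 (0.0404). With the total count as a covariate, the Dlk1-Dio3 (0.0264) and immune (0.0376) lists passed. Camera sets a list against all other entries, tRNA genes included, and the random lists hold miRNAs alone.

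MMT and MnCl2 differ in the form of manganese, an organometallic compound against an inorganic salt, and here also in dose and vehicle. Lysine tRNA with anticodon CTT summed to 26597 ± 413 CPM in MMT and 22226 ± 1098 in MnCl2 libraries (SD, n = 3), and its genes were higher in MMT as a list (camera adjusted p = 1.67e-05; adjusted p = 0.725 with an estimated correlation). In the fit of summed entries, most isotypes were higher in MMT than in MnCl2. Scarce entries of both classes mostly had lower values in MMT than in MnCl2. Of miRNAs at 20 CPM or less, 30 of 215 were positive (median log2 difference -0.48, and -0.20 with the total count as a covariate), as were 0 of 8 tRNA genes at that level (-0.35, and -0.22 with the covariate) and 8 of 41 at 20 to 50 CPM (-0.36 and -0.11). A fragment shared by valine and alanine tRNAs is listed as 3 overlapping piRNA entries. In MMT and MnCl2 respectively, pir-87165 was at 511.7 ± 40.4 and 373.8 ± 33.9 CPM, pir-64744 at 462.7 ± 54.6 and 322.8 ± 24.3 and pir-64745 at 577 ± 87 and 419 ± 17.2 (SD, n = 3). Their differences on the log2 scale were 0.45 (95% interval 0.18 to 0.72), 0.52 (0.20 to 0.84) and 0.46 (0.15 to 0.78), each with an edgeR adjusted p of 0.981, and the control means were 433.7, 389.5 and 530.8 CPM. As lists, the valine isotypes Val-AAC, Val-CAC and Val-TAC did not pass (camera adjusted p = 0.212, 0.175 and 0.331). Lower in MMT was miR-301b-3p, by a log2 difference of -0.79 (95% interval -1.40 to -0.19, edgeR adjusted p = 0.981). These entries were picked for their low p-values, and the intervals are not adjusted for that.

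The direct test called 0 of 1113 entries with edgeR, at a lowest adjusted p of 0.981 (22 at an unadjusted p under 0.05, 15 higher and 7 lower in MMT), and 0 with DESeq2 (26 at an unadjusted p under 0.05). At that level 23 were higher and 5 lower with RLE scaling, 17 and 13 with library totals, 14 and 26 with the total count as a covariate, and 12 and 31 without the low-count filter. Lower entries were also the more frequent without control 1 (16 higher, 34 lower), MMT 3 (7 and 10) or MnCl2 2 (6 and 21). Also higher in MMT were pir-63455 (139 ± 34.3 against 85.1 ± 8.27 CPM) and a tRNA-Lys-CTT gene on chromosome 1 (275347507 to 275347435, minus strand; 767 ± 50.9 against 615 ± 28.9). Lower were miR-6331 (60.1 ± 12.6 against 92.5 ± 15.1), miR-582-5p (87.9 ± 14.9 against 128.5 ± 21.9), miR-653-5p (25.3 ± 12.3 against 49.6 ± 8.2) and miR-3579 (68.6 ± 6.2 against 94.9 ± 12), the antisense partner of miR-380-5p. For the entries lowest in MMT against control, the difference between the compounds was -0.16 for miR-320-5p (95% interval -0.57 to 0.24), -0.14 for miR-187-3p (-0.43 to 0.15) and -0.13 for the mitochondrial leucine tRNA (-0.77 to 0.50). Camera at the preset correlation called 10 lists. Higher in MMT were the tRNA isotypes Lys-CTT (adjusted p = 1.67e-05, 17 of 19 genes positive), Trp-CCA (0.00171), Pro-TGG (0.00381), Glu-CTC and Leu-CAG (0.00477 each), Met-CAT (0.0056), Ser-TGA (0.012) and Ser-AGA (0.027). Muscle miRNAs (0.00539, 0 of 12 positive, median -0.71) and choroid plexus and epithelial miRNAs (0.0105, median -0.50) were lower. None of the 10 passed with an estimated correlation (adjusted p = 0.725 with an estimated correlation), fry called 0, and no member passed when adjusted over the list alone. Lys-CTT, Trp-CCA and Leu-CAG held whichever library was left out. Muscle miRNAs lost the call without MnCl2 2 (0.166, median -0.23) or MMT 3 (0.088, median -0.66), choroid plexus miRNAs without MnCl2 1 (0.338, median -0.40) or MMT 1 (0.14, median -0.33), and Pro-TGG and Met-CAT without MMT 3 (0.088 and 0.272, medians 0.13 and 0.06 in place of 0.21 and 0.18). Glu-CTC lost it without MMT 3 (0.109) or MnCl2 1 (0.0725), with medians of 0.08 and 0.09 in place of 0.15, and Ser-TGA without MnCl2 1 (0.158) or MMT 2 (0.0557), with 0.16 and 0.36 in place of 0.26. Ser-AGA lost it without any 1 of the 3 control libraries, MMT 1 or MMT 2 (0.0551 to 0.244), with medians of 0.25 to 0.35 against 0.28 with all libraries, and without MnCl2 1 (0.304, median 0.14). With the total count as a covariate, choroid plexus miRNAs (0.0815, median -0.31), Met-CAT (median 0.12), Ser-AGA (0.24) and Ser-TGA (0.21; adjusted p = 0.0662 each) did not pass. The remaining 15 miRNA lists had adjusted p-values of 0.0571 to 0.812 and the remaining 31 isotypes 0.0543 to 0.977. Of these, the Dlk1-Dio3 cluster passed without MMT 3 (0.000667) and with the total count as a covariate (0.00277), the erythrocyte and endothelial lists without MnCl2 2 (0.0233 and 0.0132), the Hox list without MMT 2 (0.0221) and the hypoxia list without control 2 (0.0365), MMT 2 (0.0221) or MnCl2 3 (0.0124) and with RLE scaling (0.0378). Among 10000 random miRNA lists of like abundance, the medians of these lists stood at the 81.5 (Dlk1-Dio3), 32.2 (erythrocyte), 0 (endothelial), 61.2 (Hox) and 1.19 (hypoxia) percentile, and those of the called muscle and choroid plexus lists at 1.7 and 1.19. Among isotypes, Cys-GCA passed without any 1 of the 3 control libraries, MMT 3, MnCl2 1 or MnCl2 2 (0.00493 to 0.0326), Arg-ACG without control 1, control 3, MMT 2 or MnCl2 3 (0.0266 to 0.041), and Glu-TTC without MMT 2 (0.0265) or MnCl2 3 (0.0124). RLE scaling also added Cys-GCA (0.0192) and Glu-TTC (0.0436). Asn-GTT and Pro-CGG passed without MMT 2 (0.0344 and 0.0455), Gln-CTG without MnCl2 1 (0.0204), and His-GTG, Ile-TAT and Ser-GCT without MnCl2 3 (0.0216 to 0.041).

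The fold changes of the compounds against control were compared with what sharing a control group gives alone. No entry was called in both, since neither comparison called any; at an unadjusted p under 0.05, 7 were lower in both and 0 higher in both. In 100 simulations of unchanged groups, all 9 libraries were redrawn and both comparisons shared the simulated controls. A median of 4 (1 to 8.52) were lower in both and 6 (2 to 10) higher in both. Entries were drawn independently there, so copies of a tRNA did not move together as in the data, and these ranges may be too narrow. The simulated comparisons each held medians of 24 higher and 25 lower entries at that level. With the labels of the 9 real libraries redrawn 100 times, which keeps the structure between them, the medians were 2 (0 to 31.1) lower and 2 (0 to 87.1) higher in both. The summed glutamine tRNA with anticodon CTG (log2 fold changes -0.35 and -0.53) and the mitochondrial leucine tRNA (-0.97 and -0.91, summed) were lower against control with both compounds in these values. Most other summed isotypes were also lower with both. Across the 1113 entries, which are not independent replicates, the edgeR fold changes had a Pearson correlation of 0.51. On log2 CPM differences it was 0.553, against a median of 0.493 (0.434 to 0.563) in 200 simulations of unchanged groups that shared simulated controls, with entries again drawn independently. The covariance was 0.0642 against 0.0942 (0.0763 to 0.116) in the simulations, a difference of -0.0301, and 66.6% of entries had the same sign in both the data and the simulations. Redrawn labels gave a wider range, with a median covariance of 0.0484 (-0.0249 to 0.339) and correlation of 0.523 (-0.195 to 0.9), and the observed values lay within it. With 3 controls, a split would leave fewer than 2 in a part, so they were not split, and part of any excess may come from the shared controls. Leaving out MMT 2 gave a correlation of -0.00352 and leaving out control 3 gave 0.845.

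Choroid plexus and ependymal miRNAs varied between libraries of every group. miR-204-5p, typical of choroid plexus epithelium, ran from 200.9 CPM in MMT 2 to 1922 in MMT 3, and miR-1298 from 41.7 in control 1 to 1196 in MMT 3, a ratio of 28.7. miR-448-3p ran over a ratio of 11.3, and the cilia-associated miR-34c-5p and miR-34b-5p over 4.41 and 5.56. MMT 3, MnCl2 1, control 2 and control 3 held the highest levels of miR-204-5p. In the RefSeq annotation used here, the genes of miR-448 and miR-1298 lie within Htr2c, a serotonin receptor gene with high expression in choroid plexus.

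**Figure D5:**
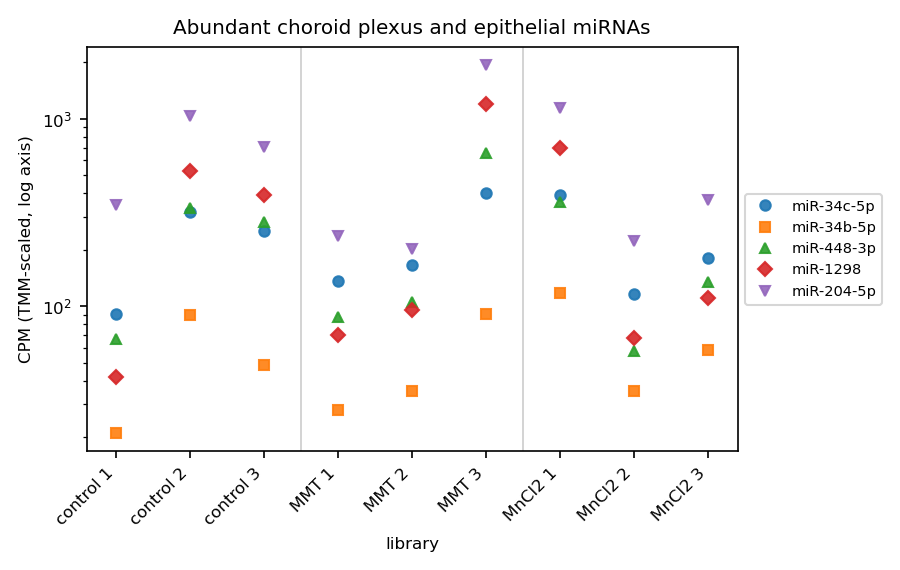
CPM (TMM-scaled, log axis) of the 5 choroid plexus and epithelial miRNAs with a mean over 50 CPM, in each of the 9 libraries, with lines between the groups. MMT 3 and MnCl2 1 hold the highest values of all 5, and miR-1298 ranges from 41.7 to 1196 CPM.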

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

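The total count as a covariate and the summing of entries that share sequence were chosen after the data were seen. The call counts of 0 entries held under every alternative in each comparison, with 1 exception: MnCl2 against control gave 1 call with no low-count filter (miR-200a-3p), and the cause was not tested. The stricter filter removed no tested entry and so decides nothing, and the alternatives for normalized values did not apply to counts. The list calls fell to 0 in all 3 comparisons with an estimated correlation and to 0 with fry, for direction and for mixed changes; both allow for the correlation between list members, and fry does not compare a list with other entries. The correlation's median was 0.153 in miRNA lists and 0.417 in isotypes. With each library left out in turn, the calls ran from 1 (without control 1) to 10 (without control 3) in MMT against control, with 3 without MMT 2, from 10 (without control 1), with 11 without control 2, to 17 in MnCl2 against control, and from 8 to 16 (without MnCl2 3) in MMT against MnCl2. Asp-GTC turned from higher to lower in MMT against control without control 1 (adjusted p = 0.299), and its adjusted p ran from 5.93e-05 (without control 2) to 0.565 (without MMT 2). The correlation of the fold changes ran from -0.00352 (without MMT 2) to 0.845 (without control 3). Differences in class share, in percentage points of miRNA, tRNA and piRNA, ran from -0.386 to 3.27, -3.2 to 0.283 and -0.0731 to 0.128 for MMT against control. For MnCl2 against control they ran from 0.822 to 4.33, -4.12 to -0.724 and -0.249 to -0.0826, and for MMT against MnCl2 from -3.12 to 0.879, -0.961 to 2.85 and 0.0822 to 0.284. The causes were not tested. No pairing by replicate number was seen: same-numbered libraries of different groups had deviations correlated at -0.666 to 0.493, 4 of 9 pairs lay over 0.1, and control 1 correlated most with MMT 3 (0.656). Control 1 and MMT 3 are also the deepest libraries, at 2012769 and 1543987 counts. Such correlations may follow depth, so they cannot exclude a pairing. With the replicate block, 0 entries and 8, 14 and 12 lists passed; it ended the calls of Pro-TGG in MMT (adjusted p = 0.0732) and of Arg-TCG, Arg-TCT and Thr-CGT in MnCl2 against control (0.0569 each), and added the oligodendrocyte list in MMT (0.0327) and Arg-ACG (0.046) and Cys-GCA (0.0254) in MMT against MnCl2. It changed no other list call. With the total count as a covariate, 0 entries passed (59, 114 and 40 at an unadjusted p under 0.05, against 24, 51 and 22 without it) and 6, 14 and 7 lists did. With entries that share sequence summed, 0 passed (6, 26 and 8). Of 1134 values under alternatives of 81 list results, those of miRNA lists and of called isotypes, 855 kept direction and side of the threshold, 159 lost the call, 26 gained it, 1 reversed and 93 turned direction with no call before or after. Over all 168 list results 65 calls were gained, 39 of them of isotypes. Of 1885 values of named entries, 1667 kept both and 218 turned direction, with no call before or after. SEs were widest for scarce entries: the median SE of a log2 fold change in MMT against control was 0.73 for miRNAs at 20 CPM or less and 0.20 above 1000 CPM.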

Other observations

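Of the tests in this part, that of transcription from both strands alone had its bounds set before its result was seen; all others were chosen after. Among piRNA entries, the 3 most abundant were pir-64143, pir-64142 and pir-64141, with 15.6%, 12.9% and 9.83% of piRNA counts, all within glycine tRNA (GCC and CCC). A lysine tRNA fragment, pir-71087, followed at 7.38%, and a selenocysteine tRNA fragment, pir-64203, stood at 3.22%. The piRNA class in these striatal libraries was thus mostly tRNA sequence by count (88%). Selenocysteine tRNA itself summed to 3673 ± 964 CPM in control, 3078 ± 186 in MMT and 2810 ± 461 in MnCl2 libraries (SD, n = 3). Mitochondrial glutamine tRNA summed to 16075 ± 2391, 12922 ± 1384 and 11149 ± 929 CPM, and nuclear glutamine tRNA with anticodon TTG to 3043 ± 797, 2396 ± 165 and 2404 ± 277 (SD, n = 3; edgeR adjusted p = 0.998 and 0.993 against control for each).

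The first principal component, with 64.4% of the variance, was weighed against treatment, depth and a fixed background. Treatment accounts poorly for it: the groups held 17.1% of its variance, and 167 of 280 partitions of the libraries into 3 groups of 3 held as much (median 20.8%). Depth stays open, with a Spearman correlation of -0.983 with the total. Counts of 34 miRNAs of embryonic stem cells and testis, summed, were 139 in control 1 and 494 in MnCl2 2, with a slope on the total of -0.653 ± 0.232 (SE, log2 scale) where the 5 most abundant entries gave 1.12 ± 0.0582. The 228 miRNAs with a mean under 10 counts gave a slope of -0.426 ± 0.18 (SE). They were picked by low counts in these same libraries, which may itself lower their slope. They were also not kept apart from the 34, so the 2 sets are not separate observations. Both sets of counts thus fell as the total rose. A background of fixed size alone, which predicts a slope near 0, does not account for this fall, and the cause stays open.

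The antisense pairs of miRNA entries were weighed between reads placed without regard to strand and transcription from both strands. In 17 pairs with 1000 counts or more for each partner, the log2 ratio of counts lay a median of 0.0202 from the log2 ratio of precursor numbers. The median was 0.335 in 340 other pairs, which joined a partner to each of the 20 miRNAs nearest to it in count. That choice kept their counts alike, so 0.335 is no reference for unrelated pairs. The split between partners varied across libraries with a median chi-square per degree of freedom of 1.02, against 18.9 in the other pairs (lowest 0.274), which argues against separate transcripts. Placement without regard to strand may account for these pairs. The largest distance among these 17, 0.4, was that of miR-218a-5p and miR-218b.

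The choroid plexus miRNAs were weighed between tissue carried along at dissection, treatment and depth. The 5 abundant members moved together (median pairwise Spearman correlation 0.9, against 0.208, -0.25 to 0.633, in matched random lists). Of these, miR-448 and miR-1298 share a host gene, and miR-34b-5p and miR-34c-5p differ by 2 bases. The random lists, matched on abundance alone, do not reproduce such ties. Members of the list under a mean of 50 CPM were not part of this test. Treatment is argued against by a between-group share of 0.226%, which all 280 partitions reached, and depth by a correlation of -0.167 (Pearson -0.191; exact permutation p = 0.678 and 0.618, n = 9; Pearson 0.277 without control 1 and control 3). Choroid plexus carried along with the striatum is consistent with these values and stays open as a hypothesis, since the labels do not describe the dissection. miR-34b and miR-34c of this list are also in the miR-34 list, and the striatum may express some members itself.

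The 6 libraries of each comparison can be split in 10 ways, the real split included, too few for a share under 0.05. For MMT against control, the real split gave 0 calls and the highest other 77, 24 against 373 entries at an unadjusted p under 0.05, and 8 against 12 lists; 10, 6 and 5 of the 10 splits, the real one included, gave as many. The split that set control 1, MMT 1 and MMT 3 against the rest gave the 77 calls. These are the deepest of the 6 libraries, at 1227930 to 2012769 counts against 583045 to 1006283. The split with calls thus set deep libraries against shallow ones. For MnCl2 against control the values were 0 and 0 calls, 51 and 125 entries and 17 and 13 lists (10, 5 and 1 of the 10 splits). For MMT against MnCl2 they were 0 and 0 calls, 22 and 88 entries and 10 and 13 lists (10, 5 and 3 of the 10 splits).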
